A study of Danio rerio with 5 samples.

How the data were processed

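The data are gene-level RNA sequencing tables of 5 zebrafish caudal fin samples, 3 labelled 24h and 2 labelled Control. Per the labels' protocols, regenerated tissue was homogenised, RNA was extracted with phenol and libraries were made with a stranded mRNA kit. Per the submitters' processing notes the genome build was GRCz10; the aligner and the counting program are not given in the sources used here, nor whether counting used strand.

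Each library has its own deposited table of 31540 genes. Per the file headers, it gives whole-number counts of total, unique, exon, intron and exon-exon reads per gene, and the deposited RPKM and TPM values, which are scaled for library size and exon length. Exon and intron counts summed to the gene counts in every gene of each deposited table. The number of reads that the deposited RPKM were divided by, recovered from the RPKM, the exon reads and the exon lengths, equalled the gene reads in 24h replicate 1 and was 1.10 times the gene reads in the other libraries, so that the authors' RPKM were not made alike in all libraries. Gene names are those of the deposited tables; 26073 of the 31540 identifiers also had an entry in a table of gene names, which was used for some list members and for names that the tables mark as shared by several copies. Coordinates are those of the deposited tables, on GRCz10.

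The total gene reads were 22014754, 22341452 and 14958600 in the 24h libraries and 18887167 and 15448344 in the Control libraries. Of these, 94.0% to 95.0% were unique, 7.22% to 7.86% were intron reads and 3.08% to 3.72% came from the mitochondrial genome; the 20 most abundant genes held 13.9% to 15.3% in the 24h libraries and 17.2% to 17.4% in the Control libraries. In all pairs of libraries the counts differed by more than sampling noise (chi-square per degree of freedom 15.2 or more), so no library was counted as a copy of another. For a named gene with 1 to 3 reads in a group, the ratio of pooled reads is given with its counting interval. PCR copies were not marked, so counting intervals cover counting error only.

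The main test, fixed before the data were examined, was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on total gene reads of all 5 libraries, with TMM scaling, filterByExpr, robust dispersion and Benjamini-Hochberg adjustment at 0.05. The filter left 19034 genes and removed at most 0.107% of a library's reads. Fold changes are 24h minus Control on the log2 scale with their standard errors, CPM are scaled with the TMM factors, and the common biological coefficient of variation was 20.2%. The standard errors (SE) are approximate: the size of the log2 fold change divided by the square root of the F statistic. The labels give no replicate numbers shared between the groups, no batch and no animals, so no covariate was used.

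The 32 gene lists were also fixed before the data were examined: tissue and cell type markers, signalling pathways, metabolism and the mitochondrial genome. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists. With an estimated correlation 0 lists passed camera, where 5 had an unadjusted p under 0.05, and a directional test (fry) that asks only whether a list's genes move one way, without comparing them with other genes, passed 14. Among these, 4 did not pass camera, each in the lower direction: osteoclast signals (fry adjusted p = 0.00084), nerve and glia (0.0048), matrix remodelling (0.016) and Wnt (0.018). The median, the mean or the camera direction differ in sign in the osteoclast, blastema, keratinocyte, mucous cell, inflammation, Fgf, Bmp and retinoic acid lists, none of which passed camera.

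Named genes followed a rule set beforehand: the 8 largest fold changes in each direction among called genes with a mean log2 CPM of 3 or more, a gene symbol that is not a clone name and groups that do not overlap; the 2 members of each list with the smallest p; and acp5a, acp5b, ctsk, mmp9, csf1ra and tnfrsf11a. This gave 80 genes, of which 74 passed the test. Other members of lists were chosen as examples after their values were seen.

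The code was tested on simulated data for this comparison, with 18575 genes drawn from the means of these libraries. It recovered 45 of 100 genes changed by a log2 fold of 1 and 98 of 100 changed by a log2 fold of 2. It made 21 false calls, more than 5% of its calls, while limma-voom made 19 and DESeq2 47. The genes changed were a far smaller share than the 24.3% of tested genes called in the data. The adjusted threshold was therefore stricter in the simulation, and its recovery need not hold for the data. A list shifted by 1 was found, and no other list was called. Genes were simulated as independent of each other, so this could not show how correlation between genes affects camera. In the data the estimated correlation reached 0.75, in the macrophage list.

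Alternatives were DESeq2 size factors, other low-count filters, unique reads, leaving out each library, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, limma on log2(RPKM + 1) and log2(RPKM + 0.1) of genes with RPKM of 1 or more in at least 2 libraries, and edgeR's test against a fold change of 1.5. Exon reads, limma on log2(TPM + 1), leaving out the 20 most abundant genes of each library and rescaled RPKM were added after seeing the data. Leaving out a Control library leaves a single sample there, which is assumed to vary like the 24h libraries. Fold changes from RPKM or TPM with a pseudocount understate the change of low genes. Exon-exon reads were not tested. The intron reads were tested with the same edgeR test, and genes with exon and intron reads with an edgeR model of both kinds of reads in which each library has its own level. Tables were joined with Python 3.11.15.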

Results

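Gene expression was measured by RNA sequencing in regenerating caudal fins of zebrafish, the tissue that regrows after the tail fin is cut. The labels place 3 libraries in a group named 24h and 2 libraries in a group named Control, and describe the material of both as regenerated fin tissue. The series compares fins at 1 and 3 days after amputation. The labels do not say what the Control samples are, so every value below is read only as 24h against Control. The 24h libraries held 22014754, 22341452 and 14958600 reads in genes and the Control libraries 18887167 and 15448344. Levels are given as CPM, reads scaled to the library size with TMM factors. The labels do not state that the samples came from separate animals, so the p-values measure the spread between these samples, which may be technical. Correlations of log2 CPM across genes, which are not independent replicates, lay between 0.975 and 0.987 within a group and between 0.916 and 0.927 across groups.

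The question of the comparison is how expression differs between the groups, in a study whose title concerns osteolytic structures positive for tartrate-resistant acid phosphatase in the branching fin rays. Genes of bone formation, connective tissue, melanophores and blood vessels were lower in the 24h libraries: 23 of 31 osteoblast, 20 of 24 fibroblast and matrix, 12 of 12 melanophore and 19 of 22 endothelial genes passed edgeR's test in that direction. The largest rises included the cytokine gene il11b and the blastema genes tph1b and fgf20a, and 9 of 16 wound epidermis genes were higher. Among 19034 genes tested, 1794 were higher and 2824 lower in the 24h libraries at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. The difference was at least 2-fold for 690 of the higher and 2176 of the lower genes, and at least 8-fold for 73 and 559. The values of the groups did not overlap in 56.8% of the genes tested, against 20% expected by chance for 3 libraries against 2. The count of 4618 genes depended on the small Control group: it was 1790 without Control replicate 1 and 2208 without Control replicate 2, and the count of higher genes was 1061 without 24h replicate 2. The split was not the same in every setting: limma on log2(RPKM + 1) of the deposited RPKM called 2207 genes higher and 2001 lower, and with 0.1 in place of 1 it called 2182 and 1894, while limma on log2(TPM + 1) called 1382 and 2423.

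The 8 genes with the largest falls, by the naming rule, included mstnb, a myostatin gene that in muscle limits growth, at chromosome 9 from 41137549 to 41141350 (GRCz10). It had 3 reads in all 24h libraries together and 1943 in the Control libraries, a ratio of pooled, library-scaled reads of 1119 (95% Clopper-Pearson interval 382 to 5431, counting error only), and it overlaps another gene model on the opposite strand. The collagen X gene col10a1a, a gene of bone-forming cells in fish, was at 28.1 ± 21.8 CPM (SD, n = 3) in the 24h libraries and 10695 ± 152 (SD, n = 2) in the Control libraries, a log2 fold change of -8.58 ± 0.79 (SE), or -9.38 without 24h replicate 3, its highest 24h value. It lies on chromosome 17 from 15534144 to 15538929. The gene hpdb, of an enzyme of tyrosine breakdown, had 4 reads in the 24h libraries and 2108 in the Control libraries, a ratio of 911 (95% Clopper-Pearson interval 355 to 3345, counting error only). Its fitted log2 fold change of -9.68 became -11.04 without 24h replicate 3, and that of mstnb went from -10.001 to -10.82 without 24h replicate 1. The other 5 were wfikkn2b (log2 fold change -9.01), of a family that binds myostatin, mamdc2b (-8.92), cfd (-8.79), the complement factor D gene, sfrp2 (-8.47), a secreted Wnt modulator, and col5a2b (-8.38), a fibrillar collagen. The adjusted p of these 8 genes ran up to 0.0011.

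Among the 8 genes with the largest rises, the liver-intestine cadherin gene cdh17, on chromosome 16 from 26900740 to 26929356, was at 17.4 ± 5.65 CPM (SD, n = 3) in the 24h libraries and 0.231 ± 0.326 (SD, n = 2) in the Control libraries, from 988 and 7 reads, with a log2 fold change of 6.33 ± 0.74 (SE). The 7 reads all lay in Control replicate 2, and without Control replicate 1 its log2 fold change was 5.21. The others were plcxd3 (5.07), the cytokine gene il11b (4.97), the integrin gene itga2.3 (4.61), which overlaps isl1l on the same strand, tph1b (4.42), ggt1a (4.17, or 4.86 without Control replicate 2), EFCC1 (3.83) and fgf20a (3.67). The tryptophan hydroxylase gene tph1b, on chromosome 7 from 32835182 to 32843734, had 525 ± 88.4 CPM (SD, n = 3) against 24.6 ± 5.09 (SD, n = 2). The gene of the fibroblast growth factor Fgf20a, which is needed to start fin regeneration, is on chromosome 1 from 15700140 to 15701877 and had 67.1 ± 4.80 CPM (SD, n = 3) against 5.28 ± 0.744 (SD, n = 2). The adjusted p of these 8 genes was at most 0.0031.

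**Figure D1:**
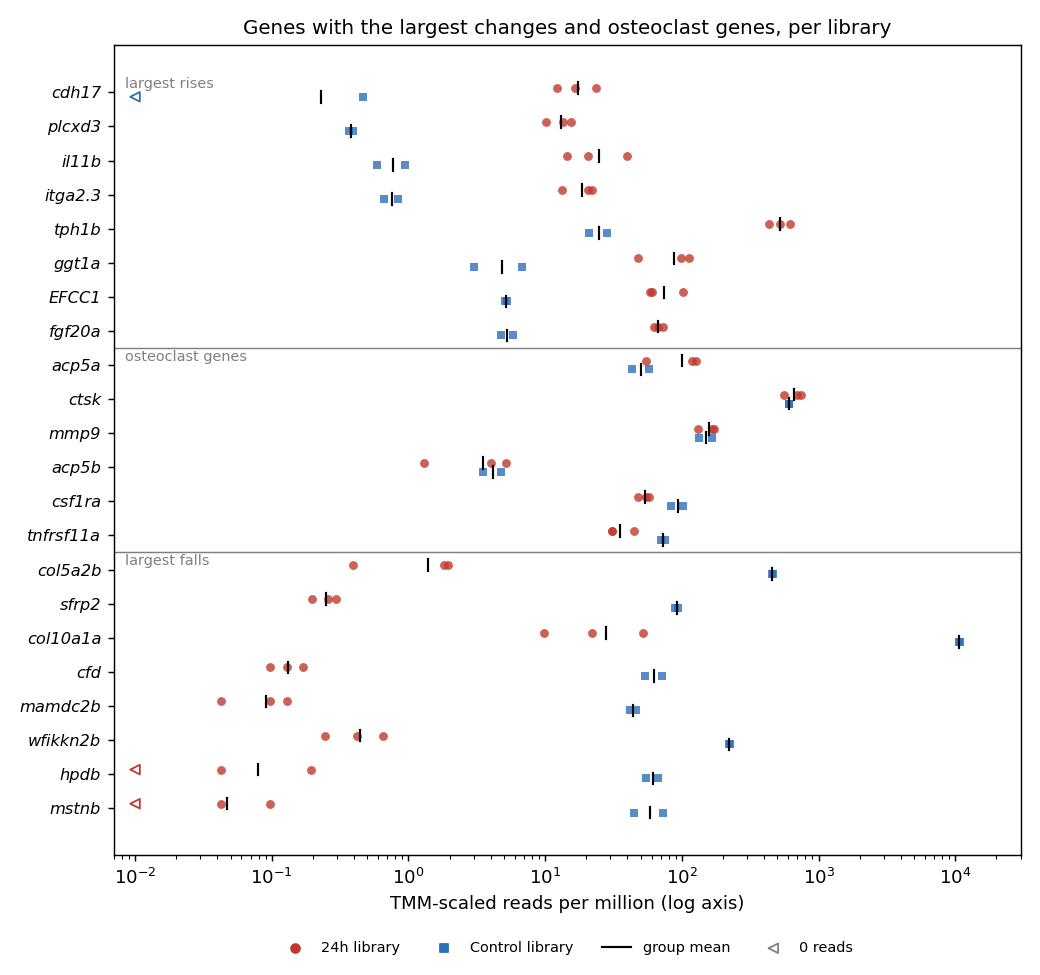
TMM-scaled CPM on a log axis for the 8 genes with the largest falls, 6 osteoclast genes and the 8 genes with the largest rises. Each point is a library (3 labelled 24h, 2 labelled Control), black bars are group means and open triangles mark libraries with 0 reads; ctsk and mmp9 sit close together in both groups, while col10a1a runs from a mean of 28.1 to 10695.

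Genes of bone-forming cells were lower in the 24h libraries. Of 31 osteoblast genes tested, 23 were lower and 2 higher, with a median log2 fold change of -2.04, and the same 23 and 2 counted when adjusted over the list alone. Beside col10a1a, the falls included ifitm5 (-7.11), a gene of mineralising osteoblasts, postna (-7.08), encoding a periostin, entpd5a (-6.31) and phospho1 (-4.19), which act in mineralisation. The transcription factor gene sp7 was lower by a log2 fold change of -2.40 and the type I collagen gene col1a1a by -2.50, while runx2a (0.43) and runx2b (-0.36) did not pass the test. The 2 higher members were dlx5a (2.14), a homeobox gene that the wound epidermis list also holds, and cyp24a1 (1.88), an enzyme that breaks down vitamin D. The list passed camera with the preset correlation (adjusted p = 6.7e-10) and did not pass with an estimated one (adjusted p = 0.186 with an estimated correlation).

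Osteoclast genes, by contrast, gave no joint direction. Of 23 tested, src (0.82) and itgb3b (1.03) were higher, and csf1rb, tcirg1a (-1.30), tnfrsf11a and csf1ra were lower, with 17 not past the test and the same counts adjusted over the list alone (camera adjusted p = 0.942). The level of tcirg1a was low, at 1.33 CPM in the 24h and 3.24 in the Control libraries. Its copy tcirg1b, at 92.2 and 71.4 CPM, did not pass edgeR's test (0.37, adjusted p = 0.072). The tartrate-resistant acid phosphatase gene acp5a had 100 ± 39.4 CPM (SD, n = 3) in the 24h libraries and 50.2 ± 10.01 (SD, n = 2) in the Control libraries, a log2 fold change of 1.00 ± 0.37 (SE) with an adjusted p of 0.095 in edgeR. It passed the threshold without 24h replicate 3 (1.296, adjusted p = 0.0028) and in DESeq2 (adjusted p = 0.022), and its adjusted p over all alternatives ran from 0.0028 to 0.400. Its copy acp5b differed by -0.22 ± 0.51 (SE), cathepsin K gene ctsk by 0.13 ± 0.16 (SE) and mmp9 by 0.07 ± 0.17 (SE), none past the test. The receptor genes tnfrsf11a, which encodes RANK, and csf1ra were lower by log2 fold changes of -1.04 ± 0.18 and -0.80 ± 0.15 (SE), with adjusted p of 0.0069 and 0.0081. The first lost the call without Control replicate 1 (adjusted p = 0.054) and the second without Control replicate 2 (adjusted p = 0.077). For csf1rb (-2.87) 94.0% of the reads were intron reads and another gene model overlaps it on the same strand. Of 8 genes in the osteoclast signals list, cxcl12a (-3.63), csf1b (-2.24), cxcl12b (-1.43) and tnfsf11 (-1.23), which encodes RANKL, were lower. The decoy receptor gene tnfrsf11b (0.90) was higher. These calls held when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.069). By fry, which makes no comparison with other genes, this list of signals was lower (adjusted p = 0.00084).

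Genes of the blastema, the mass of progenitors under the wound epidermis, moved both ways. Of 30 tested, 10 were higher, among them tph1b, fgf20a, the homeobox gene msx2b (2.77) and the retinoic acid synthesis gene aldh1a2 (2.65). Another 6 were lower, among them and2 (-5.31 ± 0.16, SE) and and1 (-3.51 ± 0.22, SE), which encode proteins of the actinotrichia, the fibrils at the fin edge. Adjusted over the list alone the counts were 11 and 9, and the list as a whole did not pass (camera adjusted p = 0.530). Of 16 wound epidermis genes, 9 were higher and 2 lower, 10 and 3 when adjusted over the list alone. The higher ones included il11a (2.84), fn1b (2.12), a fibronectin, and the collagenase gene mmp13a (1.99), and the lower ones were sema3aa (-3.69) and lamb1a (-0.82). This list passed camera (adjusted p = 0.013, or 0.533 with an estimated correlation) and did not pass without the 20 most abundant genes of each library (adjusted p = 0.065). That setting also takes such genes out of the lists, and the higher members fn1b and apoeb were at 11911 and 7953 CPM in the 24h libraries. Why the call was lost was not tested. Skin epithelium genes split evenly, with 9 of 32 higher and 9 lower (11 and 9 adjusted over the list alone, camera adjusted p = 0.910). The keratin genes krt18 (2.29) and krt97 (2.21) were higher, and krtt1c19e (-7.35) and the laminin gene lamb4 (-4.43) were lower. Of 6 mucous cell and ionocyte genes, atp1b1b (2.07) was higher and muc5.1 (-2.67), a mucin gene, lower, 1 and 2 when adjusted over the list alone (camera adjusted p = 0.631). The mucin gene lost its call when either Control library or the first or second 24h library was left out (adjusted p = 0.056 to 0.186) or no low-count filter was used (0.104), and atp1b1b without Control replicate 1 (adjusted p = 0.053).

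Positional and signalling genes also changed. Of 29 ray patterning and actinotrichia genes, 14 were lower and 5 higher (15 and 5 adjusted over the list alone). The lower ones included and3 (-4.94), hoxd13a (-3.73) and alx4a (-2.69), and the higher ones the homeobox genes dlx4a (3.09) and dlx5a (camera adjusted p = 0.018; adjusted p = 0.630 with an estimated correlation). The list did not pass without 24h replicate 3 (adjusted p = 0.085) or without Control replicate 2 (adjusted p = 0.052). Of 15 Hedgehog genes, 7 were lower, among them gli2b (-2.05) and gli3 (-1.17). The ligand gene ihhb was higher, with 63 reads in the 24h libraries and 1 in the Control libraries, a ratio of pooled, library-scaled reads of 36.5 (95% Clopper-Pearson interval 6.31 to 1463, counting error only). The counts were 9 and 2 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.630 with an estimated correlation), and the list did not pass without the low-count filter (adjusted p = 0.079). The remaining signalling lists moved both ways and did not pass camera, though by fry the Wnt (adjusted p = 0.018) and matrix remodelling (0.016) lists were lower. Of 29 Wnt genes, 11 were lower and 4 higher (12 and 4 over the list alone, adjusted p = 0.252). The lower ones included wnt16 (-4.80), which overlaps stab2 and had 35.5% intron reads, and the higher ones wnt5b (0.91). Of 30 Fgf genes, 9 were lower and 6 higher (10 and 7, adjusted p = 0.942). Among them fgfbp2a (-5.30) and the receptor gene fgfr4 (-3.34) were lower and fgf10a (2.17) higher. Of 41 Bmp and activin genes, 14 were higher and 13 lower (16 and 13, adjusted p = 0.647). The activin gene inhbab was higher by 2.93 ± 0.17 (SE) and the follistatin gene fstb by 1.83 ± 0.13 (SE), while bmp4 was at -1.64. Of 26 retinoic acid genes, 5 were higher and 7 lower (7 and 9, adjusted p = 0.942), with the retinal reductase gene dhrs3a at -6.72 and the retinoic acid breakdown gene cyp26b1 at -2.43. Of 34 matrix remodelling genes, 12 were lower and 7 higher (13 and 9, adjusted p = 0.400), with the lysyl oxidase gene loxa at -7.20, mmp11a, which overlaps upb1 on the same strand, at -6.85, and adam8a at 2.71.

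Markers of pigment cells, vessels and connective tissue were lower throughout most of their lists. All 12 melanophore genes tested were lower, with a median log2 fold change of -3.58. The melanosome genes pmela (-7.23) and tyrp1b (-6.59, or -7.21 without 24h replicate 2) led them, and 70.5% of the reads of pmela were unique to it. Of 14 xanthophore and iridophore genes, 11 were lower, including gch2 (-5.47) and aox5 (-5.30), which overlaps other gene models on the opposite strand. Of 22 endothelial genes, 19 were lower (20 adjusted over the list alone) with a median of -2.92, including vsg1 (-3.63) and the receptor gene tie1 (-3.39). Of 24 fibroblast and matrix genes, 20 were lower (22 adjusted over the list alone) with a median of -2.13, including the proteoglycan genes fmodb (-7.33) and lum (-4.54). None of these 4 lists had a higher member past the test. Their camera adjusted p ran from 5.5e-13 for the endothelium to 9.9e-07 for the xanthophores and iridophores (adjusted p = 0.186 with an estimated correlation for each). The pigment lists counted the same 12 and 11 when adjusted over the list alone.

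Of 27 macrophage genes, 3 were higher, including ctss2.1 (0.92), and 8 lower, including mpeg1.2 (-1.11), with a median of -0.12 (4 and 9 over the list alone, camera adjusted p = 0.418). The cathepsin gene ctss2.1 lost its call without Control replicate 2 (adjusted p = 0.059). Of 19 genes in the neutrophil list, nccrp1 (1.88) was higher and csf3r (-1.23) and ncf1 lower, also over the list alone (camera adjusted p = 0.840). In the 24h libraries nccrp1 was at 314 CPM, against 3.84 for mpx and 5.08 for npsn of the same list. Its rise need not come from neutrophils. The receptor gene csf3r lost its call without Control replicate 2 (adjusted p = 0.053). Of 14 lymphocyte genes, 6 were lower and none higher in the edgeR test (8 over the list alone, camera adjusted p = 0.0040; adjusted p = 0.697 with an estimated correlation), with ikzf1 at -2.29 and cd8a at -1.72. The T cell gene cd8a lost its call without Control replicate 1 (adjusted p = 0.063). Of 34 inflammation genes, 6 were higher, including il11b, il11a and il1b (1.04), and 7 lower, including steap4 (-2.75) and the inhibitor gene nfkbiaa (-0.90), with the same counts over the list alone (camera adjusted p = 0.942). Of 44 immediate early and stress genes, junba (1.65), ier2 (0.97) and hsp70.1 (1.54) were higher and 3 lower, 2 and 0 over the list alone (camera adjusted p = 0.631). The early gene ier2 lost its call without Control replicate 1 (adjusted p = 0.051). Of 9 red cell genes, 3 were lower, among them cahz (-2.37) and hbaa1 (-1.55), of whose reads 48.0% were unique. Over the list alone 5 were lower (camera adjusted p = 0.014; adjusted p = 0.630 with an estimated correlation). The globin gene hbaa1 lost its call without either Control library (adjusted p = 0.129 and 0.117) and without the low-count filter (0.065). Of 11 nerve and glia genes, sox10 (-4.53) and sncga (-2.98) were among 3 lower and 2 were higher (5 and 2 over the list alone, camera adjusted p = 0.423). Of 7 skeletal muscle genes, ckma (-3.56) was lower and tnnt3b (1.00), with 89.6% intron reads, higher, 2 and 1 over the list alone (camera adjusted p = 0.840). Both genes lost their calls without Control replicate 1 (adjusted p = 0.094 and 0.108), and tnnt3b also with exon reads (0.067) and in limma on log2(TPM + 1) (0.078).

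Of 38 ribosome biogenesis genes, 25 were higher and none lower (31 and 0 over the list alone, camera adjusted p = 9.8e-09; adjusted p = 0.630 with an estimated correlation), with the nucleolar genes npm1a at 1.23 ± 0.15 (SE), of whose reads 77.7% were unique, and dkc1 at 0.83. Of 42 lysosome and proton pump genes, 13 were higher and none lower (23 and 0, camera adjusted p = 2.0e-05; adjusted p = 0.630 with an estimated correlation), led by the cathepsin genes ctsba (1.25) and ctsd (0.68). Of 51 nuclear genes of oxidative phosphorylation, 12 were higher and 1, cox6b1 (-1.05), lower (14 and 1, camera adjusted p = 4.8e-07; adjusted p = 0.705 with an estimated correlation), with cox7a2a at 0.82 and uqcrfs1 at 0.69. Of 27 glycolysis genes, 9 were higher and 1 lower (12 and 2, camera adjusted p = 0.037; adjusted p = 0.630 with an estimated correlation), led by eno1a (1.11) and hk1 (0.85). Of 56 cell cycle genes, 2 were higher and 6 lower, also over the list alone, including stmn1a (-1.48) and the replication gene mcm4 (-0.86). Their median was -0.31 (camera adjusted p = 0.028; adjusted p = 0.904 with an estimated correlation). None of the 13 genes of the mitochondrial genome passed edgeR's test or the test over the list alone, and 0 had an unadjusted p under 0.05, with mt-nd4 at 0.28 and mt-nd1 at 0.24 (camera adjusted p = 0.494). Without Control replicate 1 or Control replicate 2, the calls of ctsd (adjusted p = 0.133 and 0.147) and uqcrfs1 (0.068 and 0.089) were lost. Those of dkc1 (0.070) and mcm4 (0.067) were lost without the first, and those of ctsba (0.059) and cox7a2a (0.068) without the second. The cell cycle list did not pass without 24h replicate 1 (0.127), 24h replicate 3 (0.098) or Control replicate 1 (0.580), nor the glycolysis list without 24h replicate 1 (0.052), 24h replicate 3 (0.094), Control replicate 1 (0.079) or the low-count filter (0.079).

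**Figure D2:**
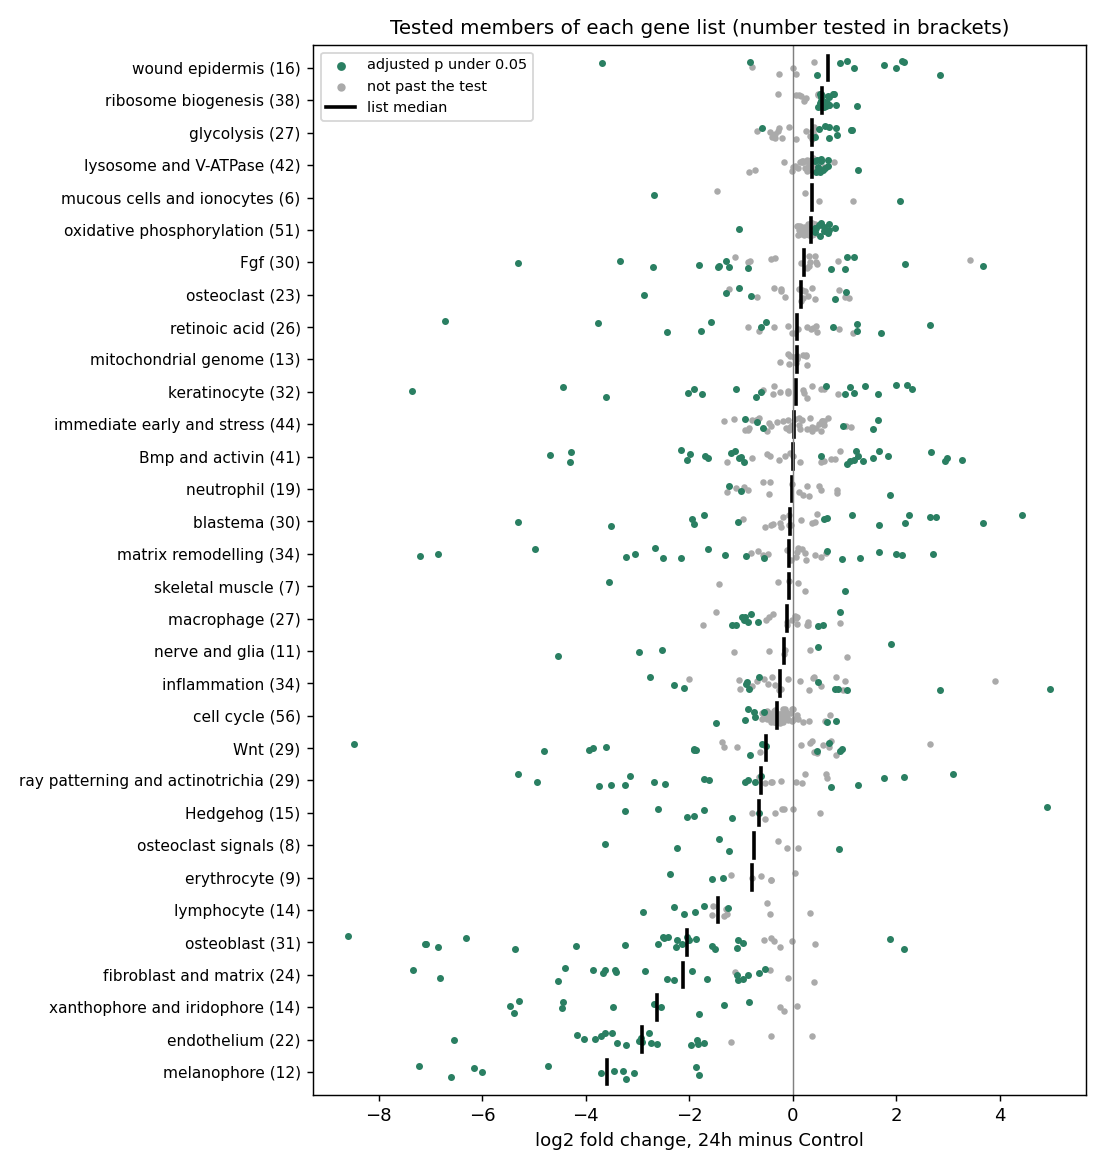
Log2 fold change (24h minus Control) of each tested member of the 32 gene lists, with the number tested in brackets, green points for genes at an adjusted p under 0.05, grey points for the others and a black bar at the list median. The melanophore list lies lowest with a median of -3.58 and the wound epidermis list highest with 0.68, and blastema genes spread from -5.31 to 4.42.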

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

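The comparison of intron with exon reads was planned before its result was seen. The test for overlapping genes was added after genes such as nt5dc1 had been seen to differ, and before the overlaps were counted.

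Intron reads, which no comparison above uses alone, also differed between the groups: by edgeR's quasi-likelihood test on intron reads, 287 genes were higher and 633 lower in the 24h libraries than in the Control libraries, of 13277 tested. Across 12221 genes with both kinds of reads, intron and exon log2 fold changes had a Pearson r of 0.773 and a Spearman rho of 0.661 across genes, which are not independent replicates, and of the 702 genes called by both 99.3% went the same way. Another 141 of the 12221 genes were called by intron reads and not by exon reads. For only 21 of them did the intron and exon changes differ in the edgeR model of both kinds of reads. The correlation fits intron reads that follow the exon reads of the gene, though not in every gene. For 120 genes (0.982%) the intron and exon changes differed. Of these, 24.2% overlapped another tested gene whose log2 fold change was at least 1 in the direction of the difference, called or not, against 1.85% of the other 12101 genes (Fisher's exact test, two-sided, p = 3.1e-23), and 24 of those 29 genes had such a partner on the opposite strand. With called partners only, counted later, it was 27 of the 120 genes and 143 of the others. Overlap with any gene was also more frequent, at 51.7% of the differing genes against 24.7% of the others. Fisher's test did not take this into account. Reads of overlapping genes counted as intron reads are thus a candidate explanation for those 29 genes, while for the remaining differing genes retained introns, unannotated transcripts and altered splicing stay open and were not tested.

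The clearest case is nt5dc1, on chromosome 20 from 484032 to 544229 on the plus strand (GRCz10), chosen after its values were seen. Its total reads fell from 2272 ± 27.4 (SD, n = 2) CPM in the Control libraries to 32.6 ± 4.79 (SD, n = 3) in the 24h libraries, a log2 fold change of -6.12 ± 0.18 (SE), yet 98.8% of its reads were intron reads, and its exon reads differed by 0.19 (adjusted p = 0.563 in edgeR) against -6.74 for the intron reads. A second collagen X gene, named COL10A1 in the files, lies inside it on the minus strand from 494770 to 498370 and differed by -7.85 ± 0.36 (SE), with 33.8% of its reads unique. Among all 4618 called genes, 371 (8.03%) had over 50% intron reads.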

How the results depend on the processing

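Exon reads, limma on log2(TPM + 1), leaving out the 20 most abundant genes and rescaled RPKM were tried only after seeing the data. The counts of changed genes (4618), higher (1794) and lower (2824) stayed within 1.5 times under DESeq2 size factors, both other filters, unique and exon reads, DESeq2 (5103), limma-voom, both RPKM settings, TPM and without the 20 most abundant genes. Against a fold change of 1.5, edgeR called 2058, 454 and 1604, since that test asks for more. Leaving out 1 library gave 1790 to 4693 changed, 418 to 1740 higher and 1372 to 2953 lower; the lowest counts came without Control replicate 1, which leaves 1 Control sample, followed by 2208, 621 and 1587 without Control replicate 2, and without 24h replicate 2 the higher genes came to 1061. Of the 15 gene lists past camera, 0 passed camera with an estimated correlation (5 at an unadjusted p under 0.05), 14 lists passed by fry (5 of the 15 did not), and 12 to 15 passed with 1 library left out. Of the 74 named genes called, 57 kept direction and call whichever library was left out and 71, where tested, in all settings other than those and the fold test, which ended 12 calls. Without the filter muc5.1, hbaa1 and the Hedgehog and glycolysis lists (adjusted p = 0.079 for both lists) lost their calls, and tnnt3b lost it with exon reads and TPM; acp5a gained one in DESeq2. Among genes not past the test, acp5b changed sign (-0.61 to 0.15 with 1 library left out; 0.15 without 24h replicate 3, 0.02 without Control replicate 1), as did mmp9 (-0.07 to 0.24; -0.01 without 24h replicate 1, -0.070 without Control replicate 2), and the cause was not tested. With 1 library left out, the cell cycle, glycolysis and ray patterning lists lost the call in at least 1 case. The wound epidermis list lost it in camera without the 20 most abundant genes (adjusted p = 0.065), a setting that also takes such genes out of the lists. In simulation of this design 45% of genes with a log2 fold of 1 were recovered, but far fewer genes were changed there than were called in the data. The adjusted threshold was thus stricter in the simulation, and 45% need not hold here. Depth and number of libraries were not varied. No paired analysis was possible because the labels give no replicate numbers shared between the groups.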

Other observations

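The tyrosine genes, the macrophage test, the tests on RPKM, the symbol families and leaving out the 20 most abundant genes were chosen after data were seen; the bound for the last was set before its result.

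Enzymes of phenylalanine and tyrosine breakdown, looked up because hpdb was among the largest falls, were lower in the 24h libraries. Of 7 looked up, 6 were tested and all 6 passed edgeR's test: hpdb (4 reads in the 24h libraries against 2108), tat (log2 fold change -7.12), hgd (-6.63), pah (-6.06), fah (-1.41) and gstz1 (-1.31). The phenylalanine hydroxylase gene pah went from 126 ± 17.5 CPM (SD, n = 2) in the Control libraries to 1.91 ± 0.554 (SD, n = 3) in the 24h libraries, and hgd from 99.8 ± 4.48 (SD, n = 2) to 1.03 ± 0.292 (SD, n = 3). The values of all 6 genes lay below both Control libraries in each 24h library. The groups did not overlap in 56.8% of all genes tested, and hpdb was picked for its fall, so its own call adds no support.

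Genes were also grouped by the letters that begin their symbols, which gave 177 families of 10 or more tested members, 25 of them past camera with the preset correlation and 0 with an estimated one (adjusted p = 0.907, with 1 family at an unadjusted p under 0.05). Of 43 collagen genes, 32 were lower and 4 higher, with a median log2 fold change of -2.02. Of 13 adamts protease genes, 10 were lower and none higher by edgeR's test (median -2.02), and of 21 ccl chemokine genes 10 were lower and 1 higher (median -1.57). Of 44 mrpl genes of the mitochondrial ribosome, 20 were higher and 1 lower (median 0.50), of 15 psmd proteasome genes 11 were higher (median 0.61), and of 12 timm genes of mitochondrial protein import 9 were higher (median 0.67).

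Bone, fibroblast and melanophore genes were lower together, with a median log2 fold change of -2.40 over 65 genes. Removing the trend of fold change with exon length, which breakdown of RNA would leave, kept 87.55% of that median (Spearman rho with length -0.069 across genes). Equal dilution of every non-epithelial cell type would move their markers alike, but the macrophage median lay 2.80 log2 units above the endothelium median (95% bootstrap interval 1.87 to 3.38). The bootstrap intervals here resample list members as if independent, so they cover the spread among markers and not between libraries. The macrophage list had an estimated correlation of 0.75 between genes, and this pair of lists was chosen after data were seen. The test planned for a larger share of all such tissue did not decide. Its gap of 1.476 (0.814 to 2.41) between other cell types and these genes spans the bound of 1 set for it. The test pools lists with unlike medians, endothelium at -2.92 (-3.50 to -2.30) with macrophages at -0.12 and red cells at -0.79. Nerve and glia, at -0.18, had an interval of -2.53 to 0.48 over 11 genes, which overlaps that of the endothelium. Outside this pool, the neutrophil median was -0.03 and the lymphocyte median -1.44. A larger share of bone, vessel, pigment and connective tissue in the Control libraries, arrival of macrophages in the 24h samples, and lower expression per cell cannot be told apart with these bulk libraries, and the biological difference between the labelled groups was not tested apart from them.

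More genes were lower than higher in the 24h libraries (61.2% of calls), but 47.6% were lower with the deposited RPKM. The first 24h library did not account for the majority, since 63.79% were lower without it, above the bound of 55% set beforehand. Without the 20 most abundant genes of each library 61.94% were lower, also above that bound. That test could not decide, since TMM scaling already limits the weight of a few abundant genes. Abundant Control genes that take reads would also make other genes look higher, not lower, in the 24h libraries. For the RPKM, rescaling each library to its own gene reads gave 54.25% lower, between the bounds of 50% and 55%, and adding the TMM factors gave 55.76%. The deposited denominators were nearly the same multiple of the gene reads in all libraries other than the first 24h library. Rescaling to gene reads therefore changed mainly that library against the others, and the share lower rose from 47.6% to 54.25%. The larger part of the move to 55.76% thus came with that step, and the smaller part with the TMM factors. Since 54.25% lies between the bounds, whether that denominator alone accounts for the deposited split was not decided. The RPKM setting also differs in reads, test, pseudocount and genes tested; edgeR on exon reads gave 61.05% lower and limma on log2(TPM + 1) 63.68%, while the choice of genes was not tested apart.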
